A study of Homo sapiens with 24 samples.

How the data were processed

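Poly(A) RNA of HCT116 cells was sequenced from unstranded libraries made with an Illumina mRNA kit, per the labels' protocols. Cells had received control, PGC1β or ERRα siRNA for 72 h, at a concentration the labels give as 20 uM. The submitters' processing notes name fastp 0.20.0, STAR 2.7.3a, SAMtools 1.10, HTSeq 0.11.2, DESeq2 1.22.1 and MultiQC 1.8, with no parameters, and the genome build and annotation are not given in the sources used here.

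The authors deposited 3 kinds of gene table. The 24 lane files hold raw HTSeq gene counts as whole numbers, per the file headers and values, with separate lines for reads that HTSeq assigned to no gene. The 6 gene tables hold RSEM expected counts, per the file headers, which were rounded to whole numbers here. The 2 tables of the authors' own DESeq2 comparisons hold log2 fold changes, p-values and adjusted p-values, and a mean of normalised counts (the baseMean, a score without a fixed range), per the file headers. Another 6 tables of transcript estimates were not used here.

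Samples were grouped by the labels' titles. The lanes are technical runs of 1 library, so the 4 lanes were summed and the library was the replicate (2 per group). The table has 60676 genes, and the authors' deposited tables pair all but 66 identifiers with a name. The lines for unassigned reads were left out of library sizes: reads in no gene were 3.63% to 5.3% of all reads, ambiguous reads 3.66% to 3.87% and reads aligned to several places 4.53% to 5.18%. Without strand information, reads from overlapping genes on opposite strands cannot be told apart. Positions of the targeted genes and gene types come from GENCODE release 29 (GRCh38), matched by identifier. With 14830221 to 18026205 counts per library, counting error is small beside the spread between libraries for all but the rarest genes, and floors cover counting error only.

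The main test was the edgeR 4.0.16 quasi-likelihood test (glmQLFit and glmQLFTest) in R 4.3.3 on all 6 libraries in 1 model with a mean per group, TMM normalisation, filterByExpr with its minimum count of 10 (14799 genes kept) and Benjamini-Hochberg adjustment within each of 3 comparisons, with a threshold of 0.05. There were 3 residual and 4.5 prior degrees of freedom. DESeq2 1.42.0 (Wald test, default independent filtering, all 6 libraries) was chosen beforehand as the other tool. CPM values use TMM-adjusted library sizes, and log2 CPM a prior count of 2. Standard errors beside log2 fold changes are those of DESeq2.

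The genes named follow a rule fixed before the data were examined: the targeted genes and their family, the 10 highest and 10 lowest protein-coding genes by log2 fold change per knockdown among those past the threshold with a mean of at least 5 CPM and both knockdown libraries on the same side of both controls, the 5 per direction for the difference and for shared genes, up to 4 genes per list, and PCK2, PHGDH and ASNS. Since the edgeR test called no gene, the rule was applied to the DESeq2 calls, a choice made after seeing that result. This left 278, 28 and 123 eligible genes for PGC1β siRNA, ERRα siRNA and their difference.

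The 28 gene lists were also fixed beforehand. Each of the 26 with at least 3 tested genes was compared with all other genes by camera (limma 3.58.1) with its preset correlation of 0.01, adjusted over the 26 lists of a comparison; the estimated correlation and fry were alternatives. The mitochondrially encoded mRNAs and the markers of other cell types had too few HTSeq counts for that and are given as values. The former were also tested on RSEM counts, outside the adjustment over lists. For the overlap of the knockdowns, 100 data sets without any effect were drawn, with both knockdowns set against the same simulated controls. All 6 libraries were redrawn around the control means, with the spread pooled over the groups. Another 10 such draws went through DESeq2. The scripts were tested on simulated data with 200 changed genes per knockdown in 3 runs, with the same spread in every group.

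Alternatives were RLE size factors, other filters, DESeq2, only the 4 libraries compared, RSEM counts, lane 1 alone and each library left out in turn, where the lone library of its group is assumed to vary like the other groups. The edgeR likelihood ratio test, voom with quality weights, removal of the nuclear copies of mitochondrial genes and repeats of DESeq2 under these settings and on the RSEM counts of mitochondrial mRNAs were added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.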

Results

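Messenger RNA was sequenced from HCT116 cells, an established human colorectal carcinoma line, 72 h after transfection with control siRNA or with siRNA against PGC1β or ERRα. PGC1β (gene PPARGC1B) is a transcriptional coactivator and ERRα (gene ESRRA) is an orphan nuclear receptor that such coactivators bind. The comparisons ask which transcripts differ after each siRNA, and protein levels are not part of these data. There were 6 libraries, 2 per group, numbered 1 and 2 for control, 2 and 6 for PGC1β siRNA and 7 and 8 for ERRα siRNA. Each library was run on 4 lanes, and the 24 deposited count files are those lanes. The lanes of a library agreed within sampling noise, with a chi-square statistic per degree of freedom of 1.03 to 1.05, so they were summed and each library was counted as 1 replicate (n = 2). The same ratio between the libraries of a group was 13.9 for control, 99.6 for PGC1β siRNA and 44.7 for ERRα siRNA. Total gene counts per library ranged from 14830221 to 18026205, and 22779 to 24423 genes had at least 1 count.

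The targeted genes were examined first. PPARGC1B (ENSG00000155846, chromosome 5, 149730298 to 149855022 on the plus strand of GRCh38) was at 28.1 ± 3.03 CPM (counts scaled to a common library size; mean ± SD, n = 2) in control and 11.1 ± 1.58 CPM in PGC1β siRNA libraries, which is 39.4% of control. The raw counts behind these values were 553 and 430 in control and 153 and 178 after PGC1β siRNA. In ERRα siRNA libraries PPARGC1B was at 26.4 ± 2.35 CPM, 93.9% of control. ESRRA (ENSG00000173153, chromosome 11, 64305572 to 64316743 on the plus strand of GRCh38) was at 43.0 ± 4.26 CPM in control and 5.12 ± 1.15 CPM in ERRα siRNA libraries, 11.9% of control. Its counts were 842 and 663 in control and 94 and 66 after ERRα siRNA. ESRRA differed between the PGC1β siRNA libraries, at 47.8% of control in library 2 and 105% in library 6. Of the relatives of these genes, PPARGC1A had no count in any library, ESRRG had at most 1, ESRRB had 5 to 21, and PPRC1 had 1969 to 3915. DESeq2 gave PPARGC1B a log2 fold change of -1.34 ± 0.30 (SE; adjusted p = 0.00145) after PGC1β siRNA and ESRRA one of -3.05 ± 0.43 (adjusted p = 1.89e-08) after ERRα siRNA. The edgeR quasi-likelihood test gave adjusted p = 0.21 and 0.94 for these differences, and called PPARGC1B without PGC1β library 2 (adjusted p = 0.0198) or 6 (adjusted p = 0.0438). DESeq2 lost the PPARGC1B call without control library 1 or 2, with a largest adjusted p of 0.766, and kept that of ESRRA in each of the 6 fits that left out 1 library.

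**Figure D1:**
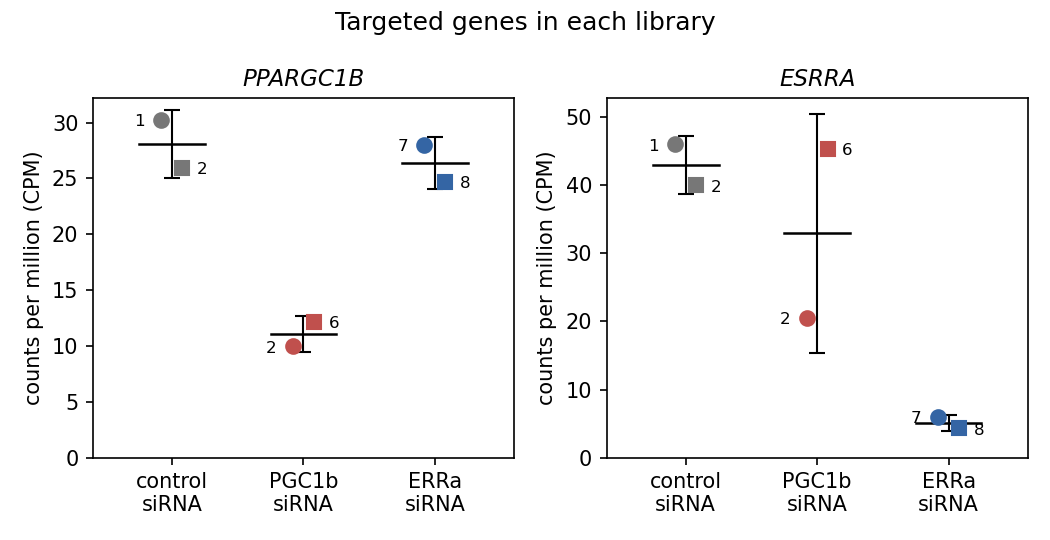
CPM (y axis) of PPARGC1B (left) and ESRRA (right) in each siRNA group (x axis). Each point is 1 library, marked with its number, horizontal lines are group means and error bars are SDs (n = 2). PPARGC1B was lowest in the PGC1β siRNA libraries and ESRRA was lowest in the ERRα siRNA libraries, while ESRRA in PGC1β library 6 was at the control level.

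The knockdown groups were far more variable than the controls. The SD of the log2 difference between the libraries of a group, over 14799 tested genes, was 0.334 for control, 0.87 for PGC1β siRNA and 0.586 for ERRα siRNA. In those pairs 260, 2859 and 1292 genes differed by more than 2-fold. The first principal component of log2 CPM, with 48.1% of the variance, set PGC1β library 6 apart at 83.2, while the other 5 libraries lay between -27.2 and -2.52. No label gives a batch. The labels also do not say whether the libraries of a group came from separate cultures or from the same siRNA. The p-values therefore weigh differences only against the spread between these libraries. In the fits on all 6 libraries that spread was estimated over the 3 groups together, although they differed in it.

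PGC1β siRNA was compared with control siRNA to find the transcripts whose level differed after it. Of the 10 lowest DESeq2 calls by the naming rule, with a mean of at least 5 CPM, PCK2, SLC1A4 and PHGDH are described first. The others are given further below. PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, was 14.9-fold lower, at 5.77 ± 0.255 CPM (n = 2) against 86.6 ± 54.5 CPM. SLC1A4, a neutral amino acid transporter, was 14.8-fold lower, at 1.82 ± 0.547 against 27.2 ± 10.4 CPM. PHGDH, the first enzyme of serine synthesis, was 5.16-fold lower, at 52.6 ± 20.5 against 273 ± 83.6 CPM. The cell cycle inhibitor CDKN1A was 7.15-fold higher, at 443 CPM in library 2 and 1913 CPM in library 6 against 186 and 145 CPM in the controls. With 1 library left out, the DESeq2 log2 fold change ran from -4.43 to -3.06 for PCK2, from -4.24 to -3.45 for SLC1A4, from -2.84 to -2.01 for PHGDH and from 1.43 to 3.53 for CDKN1A.

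The edgeR quasi-likelihood test, chosen before the data were examined, called 0 of 14799 genes at an adjusted p under 0.05 in this comparison. Its smallest adjusted p was 0.173, and 2037 genes had an unadjusted p under 0.05, where chance alone gives about 740. DESeq2, which was also chosen beforehand, called 330 genes, 158 higher and 172 lower, of which 328 had both PGC1β siRNA libraries on the same side of both controls. In simulated libraries with known changes (14487 to 14535 genes), 22.8% of the DESeq2 calls and 10.6% of the edgeR calls for this comparison were false. There edgeR recovered 66.7% of 4-fold changes and 8.16% of 2-fold changes. Every simulated group had the same spread for a gene, unlike the real groups, so these rates need not hold for the data. The DESeq2 count depended on single libraries: it was 18 without control library 1, 19 without control library 2, 2156 without PGC1β library 2, 614 without PGC1β library 6, 214 without ERRα library 7 and 204 without ERRα library 8. The edgeR count was 2131 without PGC1β library 2, 174 without PGC1β library 6 and 1 without control library 2. Genes are named here from the DESeq2 calls, with the DESeq2 log2 fold change ± SE.

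The 24 measured genes of the ATF4 amino acid response, the programme that cells switch on when amino acids run short, had a median log2 fold change of -1.0. DESeq2 called 10 of them lower and none higher, and 14 did not pass. Adjusted over the list alone, edgeR called 15 lower. The list differed from other genes by camera with its preset correlation (adjusted p = 5.86e-17), and its adjusted p was 0.487 with an estimated correlation. Along with PCK2 (-3.90 ± 0.45, adjusted p = 4.32e-14) they included ASNS, asparagine synthetase (-2.27 ± 0.47, adjusted p = 0.000372), CHAC1, a glutathione-degrading enzyme (-2.91 ± 0.58, adjusted p = 0.000218), and TRIB3, a pseudokinase (-1.79 ± 0.34, adjusted p = 5.92e-05). The list median was -1.25 in library 2 and -0.875 in library 6. The control libraries differed in the same genes, with a median of -0.47 for library 2 minus library 1, and PCK2 was at 125 CPM in control library 1 and 48.1 CPM in control library 2. In fits that left out 1 library DESeq2 kept PCK2 throughout. It lost ASNS without control library 1 or 2 (largest adjusted p = 0.491), CHAC1 without control library 1 or PGC1β library 2 (0.121) and TRIB3 without control library 1 (0.38).

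Serine and one-carbon metabolism (14 genes, median -0.48) had 13 genes with a lower estimate, and DESeq2 called PHGDH (-2.37 ± 0.42, adjusted p = 1.17e-05), PSAT1 (-2.00 ± 0.40, adjusted p = 0.000166) and MTHFD2 (-1.40 ± 0.29, adjusted p = 0.000416) lower. Glutamine and phosphoenolpyruvate metabolism (18 genes, median -0.25) had 4 genes called lower: PCK2, ASNS, the alanine aminotransferase GPT2 (-1.78 ± 0.32, adjusted p = 1.69e-05) and the glutamine transporter SLC1A5 (-1.05 ± 0.27, adjusted p = 0.00818). Adjusted over the list alone, edgeR called 4 lower in the first list, and 6 lower and 1 higher in the second. Camera gave adjusted p = 3.22e-06 and 0.000245 for these lists, and 0.487 and 0.546 with an estimated correlation. PHGDH, PSAT1, PCK2 and ASNS belong also to the ATF4 list, so the 3 lists are not independent. DESeq2 lost PHGDH, PSAT1 and GPT2 without control library 1 (adjusted p = 0.073, 0.283 and 0.316), and MTHFD2 and SLC1A5 without control library 1 or 2 (largest adjusted p = 0.662 and 0.974).

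DNA replication and G1/S genes (24 measured) had a median of -1.35 and mitosis and G2/M genes (22 measured) a median of -1.28, while the 22 p53 targets had a median of 1.26. DESeq2 called 2 replication genes lower, POLA1, the catalytic subunit of DNA polymerase alpha (-1.51 ± 0.41, adjusted p = 0.0166), and MCM3, part of the replicative helicase (-1.33 ± 0.38, adjusted p = 0.0257). It called 0 of the mitosis genes, of which TOP2A was at -1.49 ± 0.60 (adjusted p = 0.18). Among p53 targets, 8 were called higher, including CDKN1A (2.84 ± 0.55, adjusted p = 9.85e-05), BTG2 (1.97 ± 0.34, adjusted p = 9.14e-06), FAS (1.98 ± 0.45, adjusted p = 0.00219) and TP53INP1 (2.91 ± 0.63, adjusted p = 0.000843). Adjusted over the list alone, edgeR called 7 replication genes lower and 1 higher, 0 mitosis genes and 11 p53 targets higher. Camera gave adjusted p = 3.35e-14, 4.06e-10 and 6.55e-12, and 0.577, 0.619 and 0.577 with an estimated correlation. The medians were -0.835, -0.50 and 0.37 in PGC1β library 2 and -2.68, -3.22 and 1.70 in library 6, so library 6 set most of their size. DESeq2 kept CDKN1A whichever library was left out. It lost BTG2 without control library 1 (adjusted p = 0.0678), TP53INP1 without control library 2 (0.0773), POLA1 and FAS without control library 1 or 2 (largest adjusted p = 0.679 and 0.373) and MCM3 without control library 1 or 2 or ERRα library 7 or 8 (0.744). The log2 fold changes in these fits ran from 1.07 to 3.68 for TP53INP1, from 1.13 to 2.51 for FAS, from 1.49 to 2.32 for BTG2, from -2.28 to -1.01 for POLA1 and from -1.98 to -0.882 for MCM3.

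Other metabolic lists called by camera with its preset correlation were fatty acid oxidation (18 genes, median -0.34), glycolysis (20 genes, median -0.31) and reported ERRα target genes (13 genes, median -0.31). In fatty acid oxidation, HADH (-1.77 ± 0.39, adjusted p = 0.00138) and CPT2 (-1.13 ± 0.31, adjusted p = 0.0207) were called lower by DESeq2. No glycolysis gene and no reported ERRα target was called. The apoptosis regulators (17 genes, median 0.42) held 1 gene called higher, BIRC3 (1.8 ± 0.48, adjusted p = 0.0145), and the cytosolic ribosome (34 genes, median 0.22) held none. Camera gave adjusted p = 0.00576, 0.021, 0.0324, 0.0209 and 0.0212 for these 5 lists in that order, and 0.619, 0.619, 0.519, 0.519 and 0.735 with an estimated correlation. The preset calls of fatty acid oxidation, glycolysis, reported ERRα targets, apoptosis regulators and cytosolic ribosome were all lost without PGC1β library 6, where the medians were -0.196, -0.122, -0.203, 0.335 and 0.00844. The call of reported ERRα targets was also lost without control library 1 (median -0.269) or PGC1β library 2 (-0.417), that of apoptosis regulators without control library 1 (0.377), control library 2 (0.397) or PGC1β library 2 (0.496), and that of the ribosome without control library 2 (0.155). The other 15 lists did not pass, with adjusted p from 0.0843 to 0.952. Among them, respiratory complex I (38 genes) had a median of -0.07, complexes II to V (39 genes) one of -0.15 and the TCA cycle list (18 genes) one of -0.18, although the citric acid cycle enzyme IDH2 was called lower by DESeq2 (-2.21 ± 0.53, adjusted p = 0.00453). Without control library 1 or 2 DESeq2 lost HADH, CPT2, BIRC3 and IDH2, with largest adjusted p of 0.376, 1, 0.721 and 0.311, and CPT2 was also lost without PGC1β library 6 or ERRα library 7 or 8.

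Among protein-coding genes with at least 5 CPM on average, the highest DESeq2 fold changes after PGC1β siRNA, beyond CDKN1A and TP53INP1, were those of the histone genes HIST2H2BE (4.19 ± 0.82), HIST1H2BD (2.61 ± 0.52) and HIST1H2AC (2.34 ± 0.57), the transcription factor SNAI2 (3.18 ± 0.72), the semaphorin receptor NRP1 (2.89 ± 0.65), C1orf116 (2.81 ± 0.48), the hemidesmosome collagen COL17A1 (2.61 ± 0.49) and AHNAK2 (2.34 ± 0.57). Reads of the histone genes can be shared with near-identical copies, so their values are uncertain, and HIST2H2BE was at 3.32 CPM in library 2 and 38.4 CPM in library 6. With 1 library left out, the log2 fold change ran from 0.81 to 3.06 for AHNAK2, from 1.78 to 3.14 for COL17A1 and from 2.47 to 3.12 for C1orf116. The lowest, beyond PCK2, SLC1A4, CHAC1 and PHGDH, were JDP2, a repressor of the AP-1 family (-2.83 ± 0.39), PEG10 (-2.65 ± 0.56), the nuclear lamina gene LMNB1 (-2.64 ± 0.47), NIBAN1 (-2.59 ± 0.57), FHL1 (-2.59 ± 0.44) and ZNF367 (-2.53 ± 0.46). Of these 20 genes, SLC1A4, PCK2, JDP2, CDKN1A and C1orf116 were called by DESeq2 in each of the 6 fits that left out 1 library. Calls lost without control library 1 were those of HIST1H2BD, HIST1H2AC, COL17A1, AHNAK2, CHAC1, PHGDH, PEG10, NIBAN1 and FHL1, and without control library 2 those of TP53INP1, HIST1H2AC, SNAI2, NRP1, AHNAK2, PEG10, FHL1 and ZNF367. CHAC1 and NRP1 were lost without PGC1β library 2, and HIST2H2BE, HIST1H2AC, NRP1, AHNAK2 and LMNB1 without PGC1β library 6. The largest adjusted p ranged from 0.0511 for ZNF367 to 0.958 for NIBAN1.

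**Figure D2:**
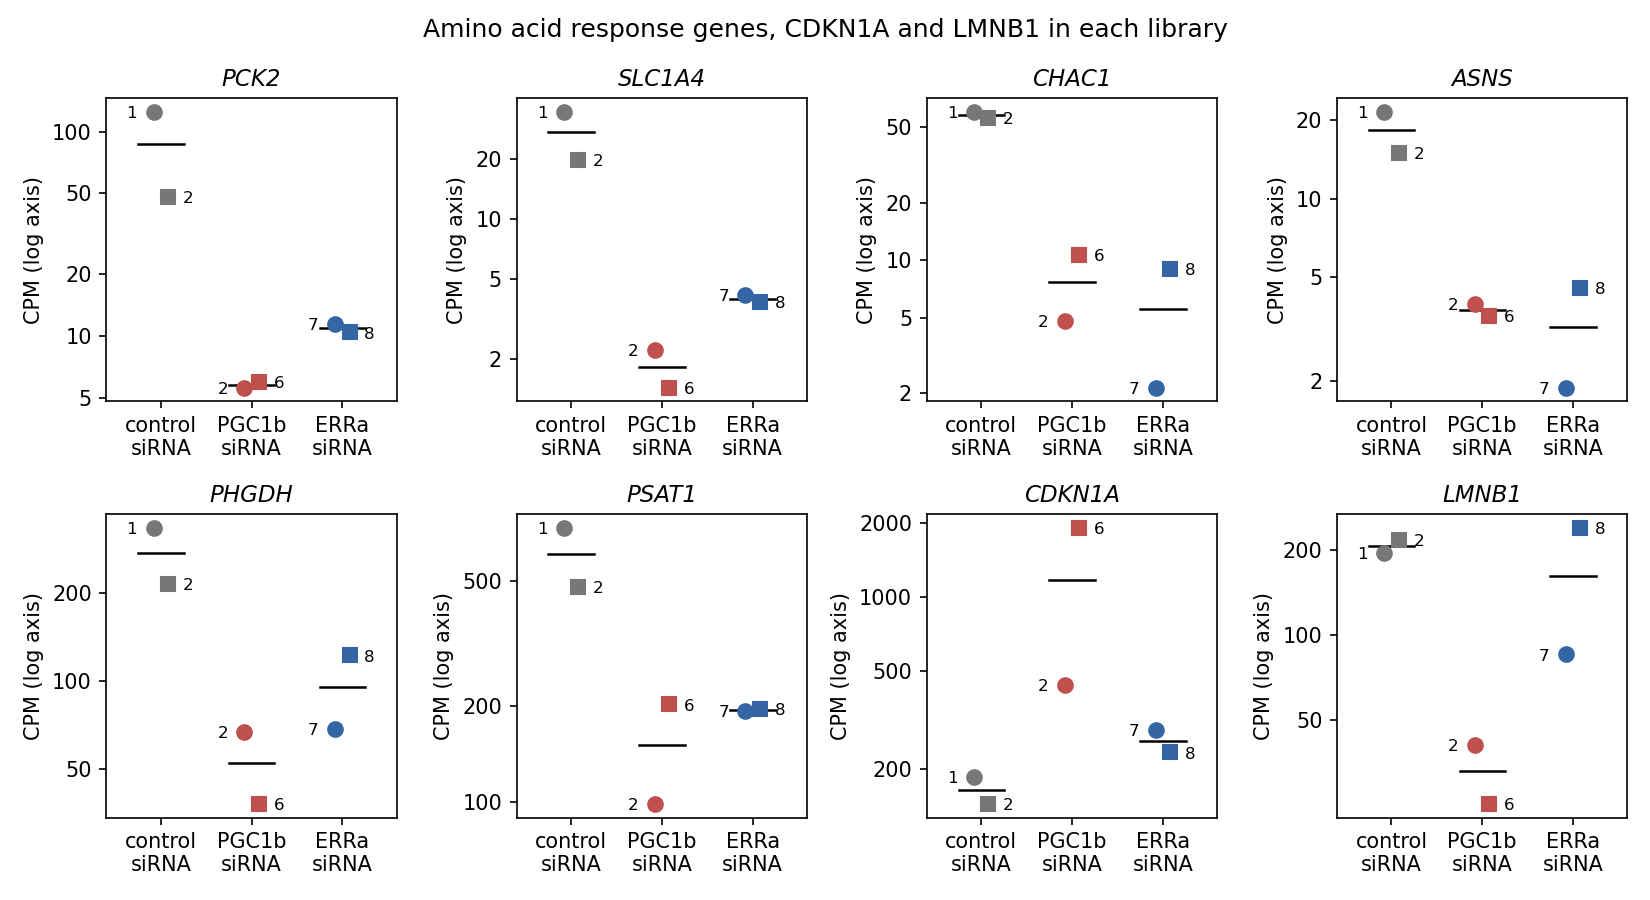
CPM on a log axis (y) of 8 genes in each siRNA group (x axis). Each point is 1 library, marked with its number, and horizontal lines are group means. In PCK2, SLC1A4, CHAC1, ASNS, PHGDH and PSAT1 all 4 knockdown libraries lie below both controls, while CDKN1A is highest in PGC1β library 6 and LMNB1 is low in both PGC1β libraries.

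ERRα siRNA was compared with control siRNA to find the transcripts whose level differed after it. Besides ESRRA, the lowest DESeq2 calls with a mean of at least 5 CPM included CHAC1, PCK2 and SLC1A4, as after PGC1β siRNA. CHAC1 was 10.4-fold lower, at 5.57 ± 4.84 CPM (n = 2) against 58.3 ± 2.99 CPM in control, PCK2 was 7.81-fold lower, at 10.9 ± 0.706 CPM against 86.6 ± 54.5 CPM, and SLC1A4 was 6.69-fold lower, at 4.01 ± 0.227 against 27.2 ± 10.4 CPM. With 1 library left out, the DESeq2 log2 fold change ran from -4.74 to -2.69 for CHAC1, from -3.49 to -2.13 for PCK2 and from -3.08 to -2.30 for SLC1A4. Cell cycle genes and p53 targets stayed near the control level, with list medians of -0.21 for DNA replication, 0.16 for mitosis and 0.10 for p53 targets. CPA4, a carboxypeptidase, was 3.39-fold higher, at 70.3 ± 20.1 against 21 ± 3.37 CPM.

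The edgeR quasi-likelihood test called 0 of 14799 genes here, with a smallest adjusted p of 0.94. Its unadjusted p was under 0.05 for 748 genes, against about 740 by chance. The spread in this test was pooled over all 3 groups and so included the PGC1β libraries, the most variable pair. A count near chance therefore does not show that ERRα siRNA had no effect. With only the 4 libraries compared, edgeR called 1 gene, ESRRA (adjusted p = 0.0186). DESeq2 on all 6 libraries called 29 genes, 14 higher and 15 lower, and all 29 had both ERRα siRNA libraries on the same side of both controls. On only the 4 libraries compared it called 150. In the simulated libraries, where every group had the same spread, 21.9% of DESeq2 calls for this comparison were false. The DESeq2 count was 1 without control library 1, 8 without control library 2, 119 without PGC1β library 2, 123 without PGC1β library 6, 54 without ERRα library 7 and 8 without ERRα library 8. The edgeR test called 1 gene, ESRRA, without PGC1β library 2 or without PGC1β library 6, at adjusted p = 0.00845 and 0.00933.

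All 24 measured ATF4 response genes had a negative log2 fold change after ERRα siRNA, with a median of -0.86. DESeq2 called 7 of them lower and 17 did not pass, and edgeR called 10 lower when adjusted over the list alone. Camera gave adjusted p = 3.99e-34 with its preset correlation and 0.251 with an estimated correlation. The called genes included PCK2 (-2.97 ± 0.45, adjusted p = 1.61e-07), TRIB3 (-1.83 ± 0.34, adjusted p = 0.000173), ASNS (-2.49 ± 0.47, adjusted p = 0.000214) and DDIT4, an inhibitor of mTORC1 signalling (-2.05 ± 0.40, adjusted p = 0.000533). Serine and one-carbon metabolism (14 genes, median -0.35) had 1 gene called lower by DESeq2, PSAT1 (-1.61 ± 0.40, adjusted p = 0.0259), and PHGDH was at -1.50 ± 0.42 (adjusted p = 0.098). Glutamine and phosphoenolpyruvate metabolism (18 genes, median -0.23) had 3 called lower, PCK2, ASNS and GPT2 (-1.70 ± 0.32, adjusted p = 0.000183). Over the list alone edgeR called 3 and 4 genes lower in these lists, and camera gave adjusted p = 2.73e-06 and 4.24e-07, or 0.251 and 0.338 with an estimated correlation. The glutamine and phosphoenolpyruvate median was -0.438 without ERRα library 7 and -0.0532 without ERRα library 8. Without control library 1, DESeq2 no longer called any of these genes, with adjusted p = 0.151 for PCK2. ASNS and PSAT1 were also lost without control library 2, TRIB3, DDIT4, GPT2 and PSAT1 without ERRα library 8 and PSAT1 without ERRα library 7, with a largest adjusted p of 1 for each.

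Of the metabolic lists after ERRα siRNA, respiratory complexes II to V had a median log2 fold change of -0.16, with 34 of 39 genes lower, and the reported ERRα target genes one of -0.35, with 12 of 13 lower. DESeq2 called none of them. Examples are COX5B (-0.61 ± 0.25, DESeq2 adjusted p = 0.731) in the former list and VEGFA (-0.59 ± 0.27, DESeq2 adjusted p = 0.903) in the latter. Fatty acid synthesis (14 genes) had a median of -0.52, with SREBF1 at -0.81 ± 0.32 (DESeq2 adjusted p = 0.697). The apoptosis regulators (17 genes) had a median of 0.27 and held 1 gene called higher, BIRC3 (2.19 ± 0.48, adjusted p = 0.00414). The epithelial to mesenchymal transition list (9 genes) had a median of 0.45 and held ZEB1 (1.34 ± 0.35, adjusted p = 0.0473). Camera called these 5 lists, with adjusted p = 0.00257, 0.023, 0.00116, 0.00257 and 0.00878, and their adjusted p was 0.485, 0.338, 0.394, 0.289 and 0.394 with an estimated correlation. Without ERRα library 8 the calls of complexes II to V, reported ERRα targets, fatty acid synthesis and the transition list were lost, with medians of -0.105, -0.128, -0.247 and -0.0506. The call of reported ERRα targets was also lost without control library 1 (median -0.223) or ERRα library 7 (-0.422), and that of the transition list without control library 2 (0.0909), PGC1β library 2 (0.296) or PGC1β library 6 (0.285). DESeq2 lost BIRC3 and ZEB1 without control library 1 or 2 or ERRα library 8, and ZEB1 also without ERRα library 7, with a largest adjusted p of 1 for both. The remaining 18 lists did not pass, at adjusted p from 0.0689 to 1, among them the TCA cycle (18 genes, median -0.18, adjusted p = 0.0689), complex I (38 genes, median -0.09, adjusted p = 0.153) and fatty acid oxidation (18 genes, median -0.104, adjusted p = 0.381).

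By the same naming rule, the highest genes after ERRα siRNA were NRP1 (2.85 ± 0.65), BIRC3, the E3 ligase SH3RF2 (1.82 ± 0.46), CPA4 (1.76 ± 0.40), SEMA7A (1.73 ± 0.41), the orphan receptor NR6A1 (1.70 ± 0.35), ZEB1, FAM214B (1.27 ± 0.32), the clock repressor CRY2 (1.2 ± 0.30) and AMMECR1 (1.19 ± 0.25). NRP1 was at 10.2 CPM in ERRα library 7 and 51.3 CPM in library 8. The lowest, beyond ESRRA, PCK2, ASNS, DDIT4 and TRIB3, were CHAC1 (-3.38 ± 0.59), SLC1A4 (-2.74 ± 0.42), the NKG2D ligand ULBP1 (-1.99 ± 0.42), JDP2 (-1.97 ± 0.38) and the cystine transporter SLC7A11 (-1.96 ± 0.43). Among these 20 genes only the DESeq2 call of ESRRA held in each of the 6 fits that left out 1 library. All 29 called genes kept their sign in those fits, which was nearly fixed in advance because both ERRα libraries lay on the same side of both controls. Their log2 fold changes ran from 1.15 to 1.23 for AMMECR1, from 1.03 to 1.35 for CRY2, from 1.31 to 2.73 for BIRC3 and from -2.64 to -1.62 for DDIT4. Leaving out a library also changes the estimate of spread, so a lost call need not mean a changed fold.

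**Figure D3:**
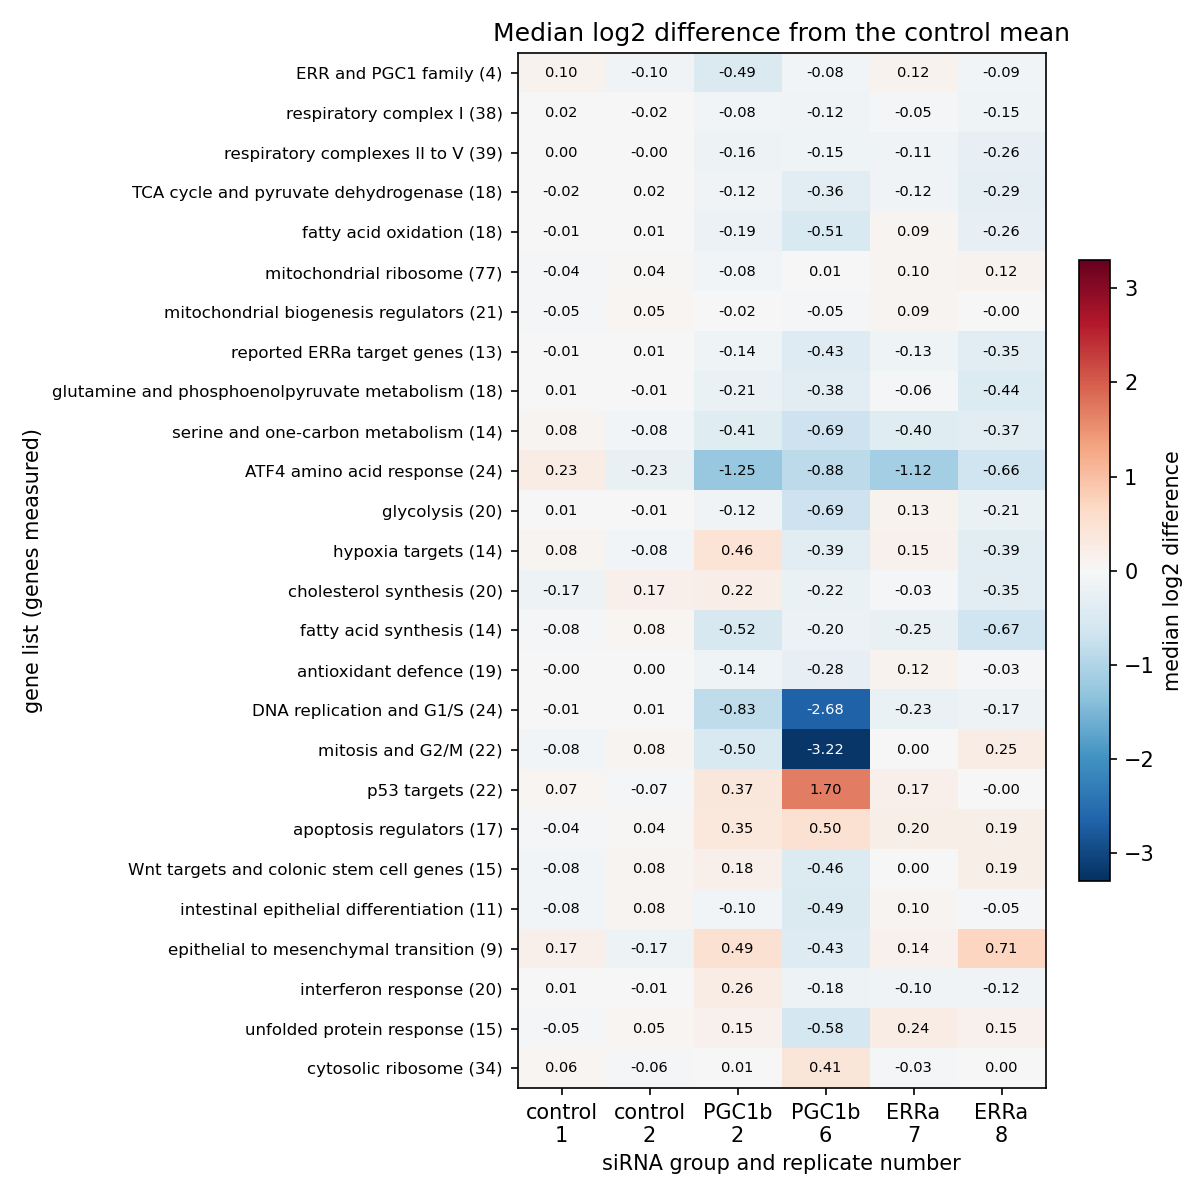
Median log2 difference from the mean of the controls for 26 gene lists (y axis, with the number of genes measured) in each of the 6 libraries (x axis, siRNA group and replicate number). Colour and printed value give the median. The ATF4 list is between -1.25 and -0.66 in the 4 knockdown libraries, and the DNA replication, mitosis and p53 lists stand apart in PGC1β library 6, at -2.68, -3.22 and 1.70.

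The knockdowns were next compared directly, ERRα siRNA against PGC1β siRNA, whose fold changes do not use the controls, although the controls share in the estimate of spread. The medians of the cell cycle lists were higher and that of p53 targets lower with ERRα siRNA, at 1.22 for DNA replication (23 of 24 genes higher), 1.4 for mitosis (22 of 22 higher) and -1.19 for p53 targets (21 of 22 lower). The adjusted p of each was 0.905 with an estimated correlation, and DESeq2 called 1 replication gene higher, 0 mitosis genes and 4 p53 targets lower. Without PGC1β library 6 the medians were 0.454, 0.602 and -0.298. ZNF367 was 5.83-fold higher with ERRα siRNA (73.4 ± 7.42 against 12.7 ± 8.55 CPM, n = 2), LMNB1 was 4.95-fold higher (163 ± 109 against 33.0 ± 11 CPM) and EIF5A2, a translation factor, was 4.23-fold higher (31.4 ± 0.969 against 7.49 ± 0.929 CPM). No difference was detected in the ATF4 list, with a median of -0.05 (camera adjusted p = 0.904), which does not show equal levels. PCK2 was at 0.93 ± 0.46 (DESeq2 adjusted p = 0.413), PHGDH at 0.87 ± 0.42 (adjusted p = 0.399) and ASNS at -0.22 ± 0.49 (adjusted p = 0.93).

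DESeq2 called 141 genes in this comparison, 75 higher and 66 lower with ERRα siRNA, and the edgeR quasi-likelihood test called 0 of 14799, with a smallest adjusted p of 0.358 and 1551 genes at an unadjusted p under 0.05. The DESeq2 count was 29 without control library 1 or 2, 1809 without PGC1β library 2, 379 without PGC1β library 6, 58 without ERRα library 7 and 26 without ERRα library 8, and the edgeR count was 1716 without PGC1β library 2 and 101 without PGC1β library 6. Besides ZNF367, LMNB1 and EIF5A2, the highest genes by the naming rule were CRABP2 (2.56 ± 0.57, adjusted p = 0.00305) and TUBA4A (2.12 ± 0.37, adjusted p = 3.8e-05). The lowest were HIST2H2BE (-3.66 ± 0.82, adjusted p = 0.00305), ABCA12 (-3.01 ± 0.74, adjusted p = 0.0097), TP53INP1 (-2.79 ± 0.63, adjusted p = 0.00338), ESRRA (-2.67 ± 0.43, adjusted p = 2.8e-06) and LONRF2 (-2.64 ± 0.68, adjusted p = 0.0157). EIF5A2, ZNF367, TUBA4A and ESRRA were called in each of the 6 fits that left out 1 library. CRABP2, LMNB1, HIST2H2BE, ABCA12 and TP53INP1 were lost without PGC1β library 6, CRABP2, HIST2H2BE and LONRF2 without ERRα library 7, LMNB1, HIST2H2BE, ABCA12 and TP53INP1 without ERRα library 8 and LONRF2 without PGC1β library 2, with largest adjusted p from 0.213 for TP53INP1 to 0.69 for HIST2H2BE. Their log2 fold changes came as near to 0 as -1.01 for HIST2H2BE, -1.42 for ABCA12, -0.954 for TP53INP1, -1.18 for LONRF2, 1.41 for CRABP2 and 1.4 for LMNB1. PPARGC1B was at 1.26 ± 0.30 (adjusted p = 0.00663), and was lost without either control or either ERRα library (largest adjusted p = 0.318).

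Camera called 7 lists between the knockdowns, and none had an adjusted p under 0.905 with an estimated correlation. Beyond DNA replication (adjusted p = 2.06e-14), mitosis (2.06e-14) and p53 targets (1.25e-11) these were glycolysis (median 0.30, adjusted p = 0.0257), the unfolded protein response (0.26, adjusted p = 0.0275), the cytosolic ribosome (-0.25, adjusted p = 0.00481) and fatty acid oxidation (0.145, adjusted p = 0.037). The last 4 were lost without PGC1β library 6 (medians -0.011, 0.0671, -0.0617 and 0.134) and without ERRα library 7 (0.103, 0.287, -0.232 and 0.132). Adjusted over the list alone, edgeR called 8 p53 targets lower, 1 replication gene and 1 glycolysis gene higher and 0 genes of the other 4 lists. The other 19 lists had adjusted p from 0.055 to 0.937.

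The overlap of the knockdown responses was then measured. DESeq2 called 7 genes higher and 12 lower in both, and 0 in opposite directions, among 11990 genes with an adjusted p in both. Among these genes 148 were called higher and 167 lower after PGC1β siRNA, and 14 higher and 15 lower after ERRα siRNA. Independent lists of these sizes would share 0.173 higher and 0.209 lower. In 10 simulations with no effect, all 6 libraries were redrawn around the control means, with the spread pooled over the 3 groups. Both simulated knockdowns were set against the same redrawn controls, and shared 1.6 genes on average and 5 at most, counted over both directions together. These simulated groups gave 10.4 and 11.5 DESeq2 calls on average, against 330 and 29 in the data, so their shared counts come from shorter lists. Under that pooled spread a number of calls near 11.5 after ERRα siRNA would arise with no effect. The real groups differed in spread, so this number need not hold for them. Among shared genes with a mean of at least 5 CPM, those with the largest mean fold changes were NRP1, CPA4, BIRC3, SEMA7A and AMMECR1 among the higher ones, and PCK2, SLC1A4, CHAC1, JDP2 and ASNS among the lower ones. Log2 fold changes of the 14799 genes, which are not independent replicates, correlated across genes with r = 0.483 (rho = 0.45). The simulated groups gave r = 0.495 on average and 0.516 at most. Shared controls and equal spread give such an r with no effect. The real groups differed in spread, and the simulation drew each gene independently. The simulated r and covariance need not hold for the data, so no conclusion on a shared response is drawn from them. The covariance was 0.135 against 0.0939 on average and 0.1 at most in the simulations, a difference of 0.041 from the average. The difference between the 2 real controls alone gave a covariance of 0.028. This left 0.107, a value that rests on those 2 libraries. The controls cannot be split into parts of 2 libraries, so part or all of the excess of shared calls may come from the shared controls. Several shared lower genes, PCK2, CHAC1 and ASNS among them, belong to the ATF4 list. The median of that list was -0.469 for control library 2 minus control library 1.

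Lists that passed in no comparison covered the rest of the biology examined. Interferon response genes (20 measured) had medians of 0.06 after PGC1β siRNA and -0.05 after ERRα siRNA, mitochondrial ribosome genes (77 measured) ones of -0.02 and 0.09, mitochondrial biogenesis regulators (21 measured) ones of -0.01 and 0.06, hypoxia targets (14 measured) ones of 0.02 and -0.06 and antioxidant defence genes (19 measured) ones of -0.17 and 0.01. Cholesterol synthesis (20 measured) was at 0.08 and -0.18, Wnt targets and colonic stem cell genes (15 measured) at 0.05 and 0.16, intestinal epithelial differentiation (11 measured) at -0.28 and -0.10 and the ERR and PGC1 family (4 measured) at -0.23 and 0.08. Of 20 marker genes of other cell types, only COL1A1 passed the count filter, with 110 to 249 counts per library, and the other 19 had at most 19 counts in any library.

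Transcripts of the mitochondrial genome could be measured in only one of the count sets. The HTSeq counts on the 13 mitochondrially encoded mRNAs were 0 in all 6 libraries. Counting error alone would allow at most 3 counts, or 2.02e-05% of a library's counts. That ceiling does not bound the share of these mRNAs, since the other count set holds many reads on them. The deposited RSEM estimates of the same libraries put 4.39% to 6.88% of their counts on those mRNAs. In HTSeq counts, 7 nuclear copies of mitochondrial genes, among them MTCO1P12 on chromosome 1 and MTND5P11 on chromosome 5, took 3.69% to 5.82%. From RSEM counts the median log2 fold change of the 13 mRNAs was 0.22 after PGC1β siRNA, with 11 of 13 higher, and -0.145 after ERRα siRNA, with 10 of 13 lower. Between ERRα and PGC1β siRNA it was -0.447, with 13 of 13 lower. Camera on the RSEM counts gave unadjusted p = 0.0287, 0.173 and 0.000485 in this order with its preset correlation. With an estimated correlation it gave 0.362, 0.563 and 0.191. The edgeR quasi-likelihood test called 0 of the 13 in each comparison, with 2, 0 and 1 genes at an unadjusted p under 0.05. DESeq2 on the same RSEM counts also called 0 in each, with smallest adjusted p of 0.251, 0.999 and 0.298.

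**Figure D4:**
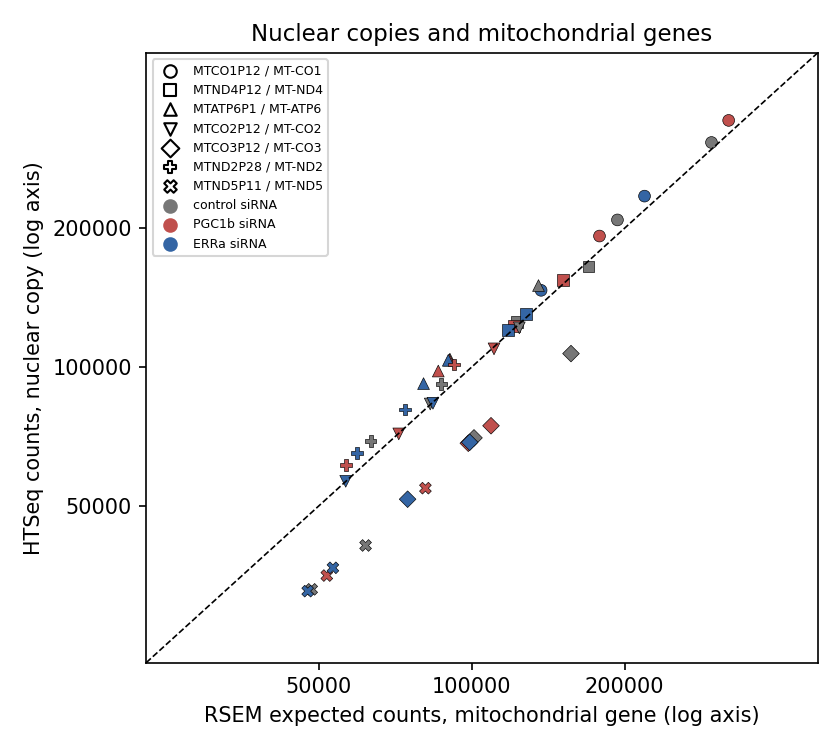
HTSeq counts on 7 nuclear copies of mitochondrial genes (y, log axis) against RSEM expected counts on the corresponding mitochondrial genes (x, log axis). Each point is 1 gene in 1 library (42 points), shapes are genes, colours are siRNA groups and the dashed line marks equal counts. The ratio of HTSeq to RSEM counts runs from 0.664 to 1.15.

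The authors' deposited tables hold their own DESeq2 comparison for each knockdown. The authors' deposited table named for ERRα has 229 genes at an adjusted p under 0.05, 106 higher and 123 lower, and the authors' deposited table named for PGC1β has 149, 75 higher and 74 lower. DESeq2 run here on only the 4 libraries compared called 224 genes for PGC1β siRNA, 103 higher and 121 lower, and 150 for ERRα siRNA, 75 higher and 75 lower. Over 14369 genes, the log2 fold changes of the table named for ERRα correlated with PGC1β siRNA against control as computed here at r = 0.9996, and with ERRα siRNA against control at r = 0.4782. Over 14223 genes, those of the table named for PGC1β correlated with ERRα siRNA against control at r = 0.9998 and with PGC1β siRNA against control at r = 0.4969. In the authors' deposited table named for ERRα, PPARGC1B was at -1.35 (adjusted p = 0.0105) and ESRRA at -0.387 (adjusted p = 0.826). In the authors' deposited table named for PGC1β, ESRRA was at -3.05 (adjusted p = 4.34e-23) and PPARGC1B at -0.0717 (adjusted p = 0.962). By these values each table holds the other knockdown than its name says, and the groups used here come from the sample labels.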

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

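Tests of GC content and length were set out before their results were seen; the other tests in this part were chosen after the result was seen.

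The direct comparison of ERRα with PGC1β siRNA differed for 7 gene lists by camera with its preset correlation, at median log2 differences of 1.4 for mitosis, 1.22 for DNA replication, -1.19 for p53 targets, 0.299 for glycolysis, 0.262 for the unfolded protein response, -0.253 for the cytosolic ribosome and 0.145 for fatty acid oxidation. None passed with an estimated correlation (adjusted p of at least 0.905).

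The first 3 lists rest mainly on PGC1β library 6, which differed from PGC1β library 2 by medians of -2.70, -2.09 and 1.36. A stronger loss of PPARGC1B in library 6 is argued against by its level there, 1.22 times that in library 2 (exact 95% interval 0.981 to 1.53, which covers counting error only and not the variation between cultures). GC content and length bias between the libraries is argued against too: after the trend with both was removed (14710 of 14799 genes had values; SD of the trend 0.0704), the medians were -2.67, -2.09 and 1.34. Against the controls, library 6 had PPARGC1B at 43.4% and ESRRA at 105%, the pattern of neither a control nor an ERRα library. The labels do not say what the numbers 2 and 6 stand for, so another siRNA or another culture stays open, and no biological explanation was tested.

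The ATF4 amino acid response list was lower than control in both knockdowns, and its control libraries differed from each other. A high ATF4 response in control library 1 alone is argued against, since the median was -0.838 for PGC1β siRNA and -0.827 for ERRα siRNA against control library 2 alone. GC content and length bias is argued against by medians of -0.956 and -0.877 once the trend was removed, against -0.986 and -0.916 before. Chance differences between so few cultures may still account for the pattern: every knockdown library lay below both controls, by at least 0.423, but the controls themselves differed by 0.469, so chance and a shared effect of the knockdowns cannot be told apart with 2 controls. An effect of losing either protein stays among the open explanations.

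The RSEM estimates, which no main comparison uses, put 6.88% of the counts of PGC1β library 6 on the 13 mitochondrial mRNAs, above both controls (4.93% and 6.34%). The missing HTSeq counts on these mRNAs are consistent with their reads being counted at copies in the nuclear genome: the median ratio of HTSeq counts on a copy to RSEM counts on its mitochondrial gene was 1.02, and 42 of 42 pairs of gene and library lay between 0.5 and 1.5. Libraries without mitochondrial reads are argued against by the lowest RSEM share, 4.39%. Of these explanations only the first is left, and the biology of these mRNAs was not weighed.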

How the results depend on the processing

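All edgeR settings here were planned except the likelihood ratio test, voom and the removal of nuclear copies, and all DESeq2 settings beyond the standard fit were chosen after seeing the data. No paired analysis was possible because the groups share fewer than 2 replicate numbers.

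The edgeR count of 0 held with RLE size factors, a minimum of 1 CPM, RSEM counts, lane 1 alone and without the nuclear copies, in all 3 comparisons (PGC1β, ERRα and their difference, in this order below). It became 946, 84 and 616 with no filter, where the prior degrees of freedom went from 4.5 to infinite; 330, 29 and 141 with DESeq2; 364, 23 and 131 with the likelihood ratio test, which ignores the uncertainty of the dispersion; 1 for ERRα with only 4 libraries and 2 with voom. With 1 library left out it ranged from 0 to 2131, from 0 to 1 and from 0 to 1716.

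DESeq2 counts stayed within 1.5 times with a filter or RSEM counts. They were 150 (ERRα) and 32 (difference) with only 4 libraries, 164, 14 and 73 with lane 1 alone, and ranged from 18 to 2156, from 1 to 123 and from 26 to 1809 with 1 library left out. All 330, 29 and 141 genes kept their sign in each leave-out. This was nearly fixed in advance and is no sign of stability. In 328, 29 and 140 of them both libraries of 1 group lay on the same side of both of the other.

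PPARGC1B kept its sign in PGC1β siRNA and passed at -1.36 with no filter, -1.34 with DESeq2 and with the likelihood ratio test, -1.19 without PGC1β library 2 and -1.5 without PGC1β library 6; no other leave-out passed. ESRRA in ERRα siRNA passed at -3.06 with no filter and with 4 libraries, -3.05 with DESeq2, -3.07 with the likelihood ratio test and -3.08 with voom. Without 1 library it was between -3.32 and -2.85, and passed only without PGC1β library 2 (-3.06) or 6 (-3.07). ESRRA in PGC1β siRNA ranged from -1.07 without PGC1β library 6 to 0.0899 without PGC1β library 2. PPARGC1B in ERRα siRNA ranged from -0.195 without control library 2 to 0.0237 without control library 1, and was 0.000357 without ERRα library 8.

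The lists called, 11, 8 and 7, were 0, 0 and 0 with an estimated correlation and 0, 0 and 0 with fry. Without 1 library they ranged from 9 to 11, from 4 to 12 and from 4 to 7. The transition list in ERRα siRNA ranged from -0.0506 without ERRα library 8 to 0.562, and glycolysis in the difference from -0.011 without PGC1β library 6 to 0.624. The correlation of the knockdowns ranged from 0.341 to 0.547 without 1 library. The cause of these moves was not tested.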

Other observations

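DESeq2 called 19 genes in both knockdowns, in comparisons that share both controls. Beyond those named there, they include the large neutral amino acid transporter SLC43A1 (-2.50 after PGC1β siRNA and -2.89 after ERRα siRNA), the fucosyltransferase FUT1 (-1.23 and -1.46) and NACC2 (1.1 and 1.09). These 3 genes were chosen after their values were seen.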
